A study of Mus musculus with 18 samples.

How the data were processed

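Omni-ATAC libraries were made from sorted precursor populations of C57BL/6 fetal liver at embryonic day 15, 18 libraries in 9 populations of 2 per the labels. CLP, LTiP and ILCP came from Zbtb16-EGFP mice and the other 6 populations from Zbtb16-EGFP Tcf7-mCherry Rorc-Thy1.1 mice, per the labels. The submitters' processing notes name Bowtie, Picard, MACS2 and bedtools with the mm10 genome, without versions, parameters or the role of each.

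The deposited count table holds raw read counts per peak and library, made by the authors over 1 merged peak set, with no normalization. It was used for 4232 complete peaks on chromosome 1 between 3104915 and 66693279, and 1 last incomplete line with 6 fields was left out. The deposited annotation table covers 214321 peaks and gives, per the file headers, nearest gene, distance to its transcription start site, GC content as a fraction of the peak's bases, and the sites of 27 motifs. The authors' GC fraction was used for binning and for a correction. All counted peaks were found in the annotation table, and they cover 349 genes. Motif matrices and thresholds are not stated, no genome sequence was used, and peaks were assigned to genes by the authors' nearest-gene annotation, which does not show that a peak regulates that gene.

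Depth was read as total reads in the counted peaks, from 135599 to 491500 per library. That total is not the library's depth. The median peak held 12 to 58 reads per library.

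Whether both libraries of a population differ beyond counting error was checked by a chi-square over peaks with at least 10 reads in the pair. Pairs within that error were given n = 1. The fit with those 5 pairs as 1 sample each (13 samples, 4 residual degrees of freedom, common dispersion 0.0129) was added after the data were seen. It first had its own TMM factors and was then changed to keep the effective library sizes of the 18-library fit, after its splits had been seen to shift. Replicate numbers were checked for pairing by the correlation over peaks of first minus second library between populations (36 pairs of populations, median −0.01, 1 above 0.1). The 1 above 0.1 was iLTiP with iILCP, at 0.20, and a pairing of those populations alone was not modelled. Elsewhere no pairing was seen, and no block was used in the main fit. For the 5 pairs within counting error this check could show little, since their deviations are mostly noise.

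Changed peaks were tested in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr over the 9 groups (60 peaks removed, 4172 tested), a robust quasi-likelihood fit of 9 group means with 9 residual degrees of freedom, and two-sided F tests with Benjamini-Hochberg adjustment within each comparison at an FDR of 0.05 and no fold minimum. The common dispersion was 0.00577, a coefficient of variation of 7.6%. The SE of a log2 change is its size divided by the square root of F. Normalised reads are counts scaled to the mean effective library of 225741. With 14 comparisons, the last was the difference between LTiP against ILCP and iLTiP against iILCP. Where leaving out a library left a population with 1 library, that library was taken to vary like the other groups.

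Gene lists, comparisons, tests and alternatives were fixed before the data were examined. Of 18 lists with 337 genes, 11 genes had counted peaks, which left 7 lists to test and 11 without a counted gene: ILC1 and NK, multipotent progenitor, B lineage, myeloid, dendritic cell, erythroid and megakaryocyte, hepatocyte, trafficking, Notch, TNF and NF-kB, and housekeeping. The lists were tested with camera (limma 3.58.1, preset correlation 0.01, and again with an estimated correlation), adjusted over 98 tests. With 1 to 4 genes each, a list's peaks are neighbours on the chromosome. Il18r1, Il18rap, Il1r1 and Il1rl1 stand in more than 1 list.

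Motif columns were grouped after the data were seen into 5 families (ROR, TCF/LEF, GATA, RUNX, ETS). A peak carried a motif when a site lay within 100 bp of its centre. Shares in higher and in lower peaks were compared with those in unchanged peaks by a two-sided exact Cochran-Mantel-Haenszel test over 10 GC bins, adjusted over 130 tests, of which 70 passed. Of these 70 calls, 50 held in the same direction with sites anywhere in the peak and 57 with pairs as 1 sample, where 2 others had too few changed peaks to test. Flt3nRORCn_aLP against Flt3pRORCn_aLP had no changed peaks to test. Peaks are not independent replicates, and other motifs fixed before the data were examined had no column and no genome to search.

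Population relations were Euclidean distances and principal components of log2 CPM with a prior count of 2 over all 4172 peaks, since the 5000 most variable peaks planned exceeded that number.

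Named peaks followed a rule: the sort loci Rorc, Zbtb16, Tcf7 and Flt3; then, among called peaks at or above the median abundance (log2 CPM, counts scaled to library size, of 6.86) with both libraries of one population above both of the other, 1 peak per nearest gene without unnamed gene models, the 10 largest rises and falls for LTiP against ILCP and for iLTiP against iILCP and the 5 largest for other comparisons; then for list members the peak with the lowest p. The sort loci had no counted peak. For the test of the difference between contrasts the criterion on both libraries could not be applied. The text gives a selection of the peaks so named, and no fold where a group held 3 reads or fewer.

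Alternatives that changed 1 choice were DESeq2 size factors, total count, no filter, only the compared groups, a fold minimum, a replicate block and each library left out. DESeq2 1.42.0 changed size factors, dispersion and test together, and cyclic loess with limma-trend changed scaling and test together. Added after the data were seen were pairs as 1 sample, a GC trend removed per library, libraries thinned to 135599 reads, the 1000 most variable peaks, the 27 motif columns singly and, for promoter peaks, limma-trend with TMM scaling. The steps were tested on simulated data, after the first fit of the real counts: for LTiP against ILCP edgeR found 16.7% of 1.5-fold, 48.1% of 2-fold and 82.4% of 4-fold changes at a dispersion of 0.005, with 3.8% false calls, and 12.2%, 36.7% and 77.6% at 0.013, with 4.9%. Simulated lists of 44 peaks with a 1.5-fold shift were found in 5 of 5 draws, and a simulated odds ratio of 3 was recovered as 3.06. Those list peaks were drawn at random with independent noise, so the draws do not test lists of neighbouring peaks that move together. Tables were prepared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.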

Results

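Open chromatin was measured by Omni-ATAC, a transposase assay whose reads pile up over accessible DNA, in sorted lymphoid precursors from the fetal liver of mice at embryonic day 15. The 18 libraries fall into 9 populations with 2 libraries each: CLP, Flt3pRORCn_aLP, Flt3nRORCn_aLP, RORCp_aLP, iLTiP, LTiP, rEILP, iILCP and ILCP. The labels do not spell out these names, and they are used as given; LTi and ILC in them are read as the lineages of the series title, and the comparisons below assume no order of populations. CLP, LTiP and ILCP came from Zbtb16-EGFP mice, and the other 6 populations from mice that also carried Tcf7-mCherry and Rorc-Thy1.1, so a comparison of a population from the first set with one from the second also compares genotypes. Per-library counts were analysed for 4232 peaks on chromosome 1 from 3.1 to 66.7 Mb (mm10), which are 1.97% of the 214321 annotated peaks. The sort loci Rorc, Zbtb16, Tcf7 and Flt3 lie outside that section, and their per-library values were not analysed here.

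Reads in the counted peaks numbered 215729 and 178669 in CLP replicates 1 and 2, 186337 and 243132 in Flt3pRORCn_aLP, 195551 and 234759 in Flt3nRORCn_aLP, and 155648 and 136506 in RORCp_aLP. They numbered 384284 and 135599 in iLTiP, 150024 and 204648 in LTiP, 198778 and 231792 in rEILP, 491500 and 197176 in iILCP, and 242329 and 250438 in ILCP. These totals cover the counted section and are not library depths. The median peak held 12 to 58 reads per library.

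Both libraries of a population were compared peak by peak against counting error. Chi-square per degree of freedom was 0.898 in CLP, 0.976 in Flt3pRORCn_aLP, 0.969 in LTiP, 1.015 in rEILP and 0.962 in ILCP, so those pairs agree within sampling noise. Each of these 5 pairs is counted as 1 sample (n = 1), and its normalised reads stand without an SD. This is a cautious choice, since the labels give 2 samples each. Such agreement does not by itself tell 1 library from 2 samples that vary little. The ratio was 1.206 in Flt3nRORCn_aLP, 1.176 in RORCp_aLP, 1.916 in iLTiP and 2.219 in iILCP, whose values are given as mean ± SD with n = 2. Every ± on a log2 change of a peak is the SE of the edgeR fit, and the ± of a median log2 change over promoter peaks is a bootstrap SE over those peaks. The p-values measure only the spread between these samples, which may be technical, and intervals cover counting error only. The fit pools the spread over all populations, although iLTiP and iILCP varied most. The p-values of comparisons with iLTiP or iILCP therefore lean on tighter pairs and can be too small. Unless pairs as 1 sample are named, the p-values come from a fit with each of the 18 libraries as a sample. That fit takes the 5 pairs as 2 samples each, which their agreement neither shows nor excludes. Counts of changed peaks are given both ways, and 21 named peaks lost their call with pairs as 1 sample. Where both populations are such pairs (LTiP, ILCP and CLP among themselves, and Flt3pRORCn_aLP against CLP), each adjusted p of a peak is given both ways too, and with pairs as 1 sample all of the spread comes from other populations.

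Across the 4172 tested peaks the nearest populations were Flt3pRORCn_aLP and Flt3nRORCn_aLP, 0.37 apart in root mean square log2 difference. RORCp_aLP lay 0.66 from Flt3nRORCn_aLP and 0.57 from iLTiP, while rEILP lay 0.68 from Flt3nRORCn_aLP and 0.82 from iILCP. LTiP and ILCP were 0.74 apart. CLP and ILCP were farthest apart at 1.29, level with Flt3pRORCn_aLP and ILCP. Single libraries of one population differed by 0.43 (ILCP) to 0.59 (RORCp_aLP and iLTiP) on the same scale, which holds counting noise that the population means average down. The leading principal component held 42.8% of the variance and the next held 14.5%.

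**Figure D1:**
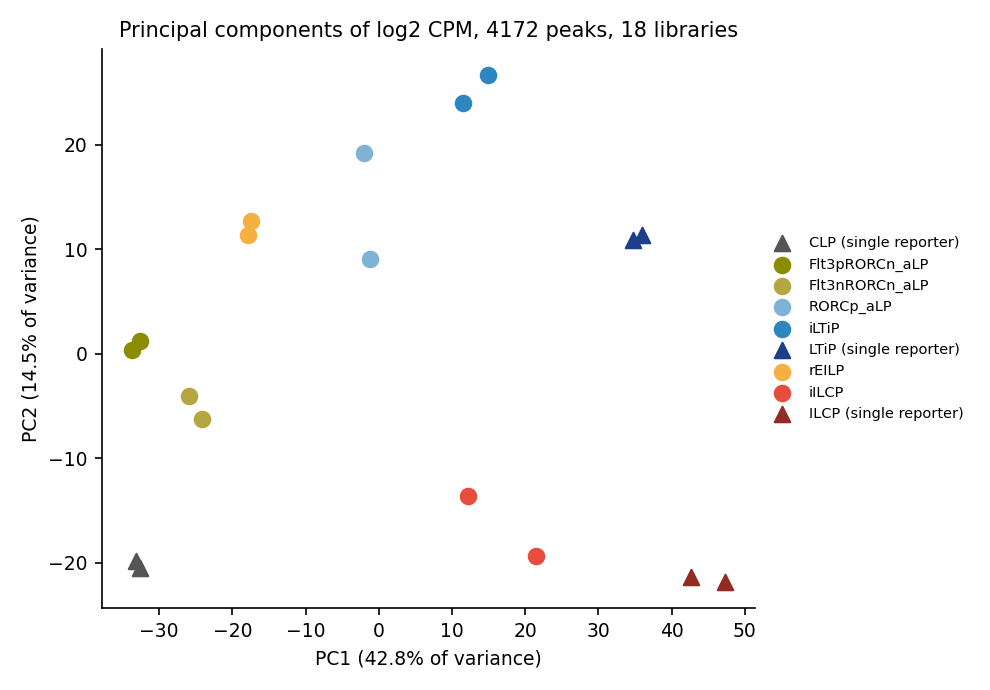
Scores of the 18 libraries on the leading principal components (42.8% and 14.5% of variance) of log2 CPM (counts scaled to library size) over 4172 peaks; each point is a library, coloured by population. ILCP libraries lie at one end of the horizontal axis and Flt3pRORCn_aLP, Flt3nRORCn_aLP and CLP at the other.

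LTiP were set against ILCP, both from mice of one genotype, to ask which chromatin differs between them. A large difference lay at Icos, a costimulatory receptor gene: the intergenic peak at 61101669–61102936, 124.4 kb from its start site, held 34.4 normalised reads in LTiP and 244 in ILCP (log2 change −2.88 ± 0.20, adjusted p = 2.06e-17, and 2.82e-10 with pairs as 1 sample). Of 29 Icos peaks, 3 were lower in LTiP and at least 1 was higher. Il1r1, the signalling receptor for IL-1, had 17 of 27 peaks higher in LTiP and 0 lower. Its intron peak at 40262499–40263700 held 354 against 179 reads (0.98 ± 0.14, adjusted p = 2.12e-07, and 0.00346 with pairs as 1 sample). At Il17f, a cytokine gene of LTi cells and ILC3, 4 of 9 peaks were higher in LTiP, among them the intergenic peak at 20759431–20760352 with 400 against 213 reads (0.91 ± 0.13, adjusted p = 3.28e-07, and 0.00324 with pairs as 1 sample). A Sntg1 intron peak at 9247977–9248825 held 73.1 against 7.08 reads (3.35 ± 0.33, adjusted p = 5.08e-12, and 4.62e-08 with pairs as 1 sample).

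Further peaks higher in LTiP were assigned to Map2, which encodes a microtubule-associated protein (log2 change 2.46 ± 0.32), to Hsfy2 (2.53 ± 0.31), to Mir6349 (2.88 ± 0.37), to Tpp2 (2.07 ± 0.33) and to Il1rl1, the IL-33 receptor gene (peak at 40409878, 1.23 ± 0.17). Mir6349 split, since another of its peaks, at 39091171, was lower in LTiP (−2.73 ± 0.31). Peaks lower in LTiP were assigned to Efhc1 (−3.38 ± 0.40), to Gtf3c3, a subunit gene of a factor for RNA polymerase III (−2.92 ± 0.30), to Rdh10, a retinol dehydrogenase gene (−2.26 ± 0.29), to Col9a1 (−2.39 ± 0.35), to Kcnq5 (−2.36 ± 0.28) and to Eya1, a transcriptional coactivator gene (−2.18 ± 0.30). Cd28, another costimulatory receptor gene, split: the peak at 60805188 was higher in LTiP (2.04 ± 0.39) and the intron peak at 60750040 lower (−2.74 ± 0.39). An Il18r1 intron peak at 40475367 was higher in LTiP by 0.61 ± 0.13, a call lost with pairs as 1 sample (adjusted p = 0.0632).

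Of the LTi and ILC3 list, whose counted members are Il1r1, Il17a and Il17f, 23 of 44 peaks were higher in LTiP and 0 lower. Adjusted over the list alone, 26 passed the threshold (camera adjusted p = 8.42e-08, and 0.0226 with an estimated correlation). Of the cytokine receptor list (Il1r1, Il1rl1, Il18r1, Il18rap), 28 of 66 peaks were higher and 5 lower, 39 when adjusted over the list alone (camera adjusted p = 7.46e-04, but adjusted p = 0.14 with an estimated correlation). The ILC precursor list (Icos, Il18r1, Il18rap) had 7 of 48 peaks higher and 3 lower, and its camera test did not pass (adjusted p = 0.656). ROR sites lay within 100 bp of the centre of 12.1% of peaks higher in LTiP and 2.4% of unchanged peaks (odds ratio 5.18, 95% interval 3.55 to 7.52, exact test, adjusted p = 5.94e-16). Peaks lower in LTiP carried more GATA sites (38.7% against 21.7%; odds ratio 2.33, 1.88 to 2.89) and more RUNX sites (44.4% against 29.5%; odds ratio 1.89, 1.54 to 2.33). For higher peaks RUNX did not pass near the centre (odds ratio 1.22, exact test, adjusted p = 0.106). With sites anywhere in the peak it did (odds ratio 1.38, exact test, adjusted p = 0.00297).

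By edgeR, 937 of 4172 peaks differed between LTiP and ILCP, 480 higher and 457 lower in LTiP. DESeq2 size factors gave 587 and 409, while the split turned to 401 and 506 under total count and to 205 and 266 with indistinguishable pairs as 1 sample. The total was 481 without LTiP replicate 2 and 594 without ILCP replicate 1.

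**Figure D2:**
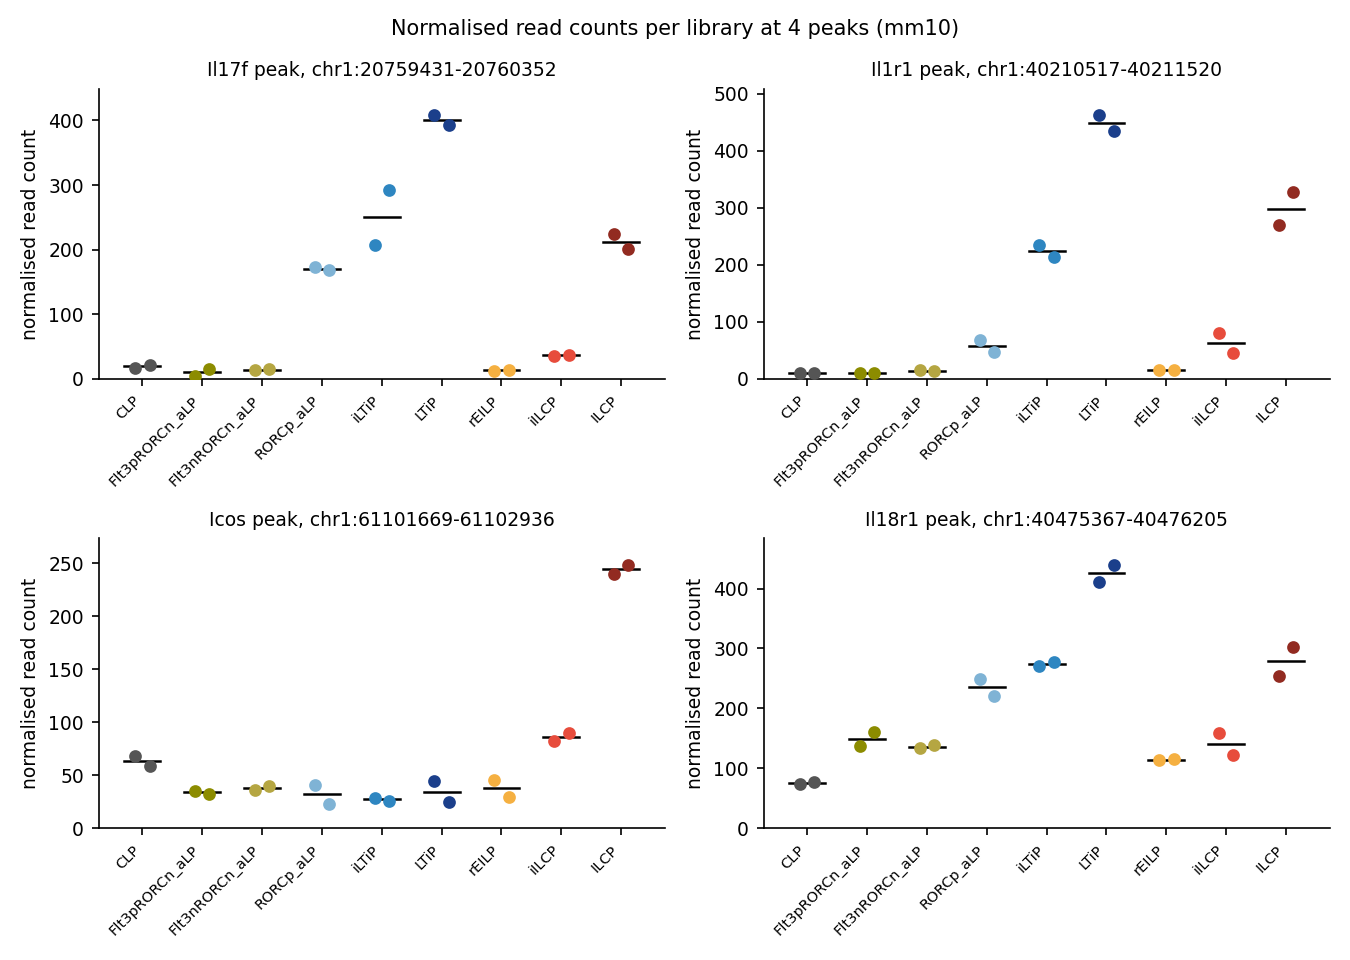
Normalised read counts (linear axes from 0) in each of the 18 libraries at 4 peaks assigned to Il17f, Il1r1, Icos and Il18r1, by population; points are libraries and bars are population means. The Il17f peak averaged 14.3 in Flt3nRORCn_aLP, 171 in RORCp_aLP, 250 in iLTiP and 400 in LTiP, and the Icos peak was highest in ILCP at 244.

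iLTiP and iILCP, both from triple reporter mice, give the same contrast between lineages in the other pair of populations. Il17f differed, with 250 ± 60.3 normalised reads in iLTiP and 36.7 ± 1.30 in iILCP at the peak at 20759431 (log2 change 2.71 ± 0.17, adjusted p = 2.99e-20). At Il17a, its neighbour and a cytokine gene of the same family, 6 of 8 peaks were higher in iLTiP; the peak at 20725511–20726175 held 74.4 ± 15.2 against 23.5 ± 8.86 reads (1.60 ± 0.22, adjusted p = 1.99e-08). Il1r1 had 14 of 27 peaks higher and 0 lower, led by the peak at 40210517–40211520, 14.1 kb upstream, with 224 ± 15.5 against 62.4 ± 24.4 reads (1.75 ± 0.15, adjusted p = 3.12e-14). Stat1, a transcription factor of interferon signalling, went the other way at its intron peak at 52150578–52151092, with 14.3 ± 4.10 reads in iLTiP and 52.1 ± 9.83 in iILCP (−2.06 ± 0.25, adjusted p = 1.28e-09).

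Other peaks higher in iLTiP belonged to Sntg1 (log2 change 3.80 ± 0.25), Col19a1, a collagen gene (3.57 ± 0.26), Prss40 (2.71 ± 0.21), Hsfy2 (2.71 ± 0.26), Mir6349 (2.43 ± 0.22), Slc9a2 (2.32 ± 0.32) and Klf7, a Krüppel-like transcription factor gene (2.24 ± 0.24). Il18r1 (peak at 40479409, 1.09 ± 0.13), Il1rl1 (peak at 40409878, 1.36 ± 0.16) and the Zap70 promoter (1.1 ± 0.16) were also higher. Lower in iLTiP were peaks of Efhc1 (−2.93 ± 0.30), Ino80dos (−2.74 ± 0.26), Rdh10 (−2.57 ± 0.25), Gtf3c3 (−2.46 ± 0.25), Eya1 (−2.37 ± 0.27) and Nrp2, a semaphorin coreceptor gene (−2.32 ± 0.25). The Mir6349 peak at 39091171 was lower too (−0.92 ± 0.24). Icos was lower at 61022270 (−2.03 ± 0.32) and at 61101669 (−1.60 ± 0.21), while 7 of its 29 peaks were higher and 7 lower. Cd28 was lower at 60776917 (−1.42 ± 0.19), with 10 of 39 peaks higher and 6 lower.

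In the LTi and ILC3 list 24 of 44 peaks were higher in iLTiP and 0 lower, 24 when adjusted over the list alone (camera adjusted p = 2.63e-13, and 0.00559 with an estimated correlation). The cytokine receptor list had 29 of 66 peaks higher and 6 lower, 35 when adjusted over the list alone (camera adjusted p = 1e-05, and 0.0417 with an estimated correlation). The ILC precursor list split, with 14 of 48 higher and 8 lower (camera adjusted p = 0.31). ROR sites lay near the centre of 10.8% of peaks higher in iLTiP and 2.3% of unchanged peaks (odds ratio 4.81, 3.33 to 6.96), and 0.4% of peaks lower in iLTiP (odds ratio 0.163). Peaks lower in iLTiP carried more GATA sites (32.7% against 20.8%, odds ratio 1.98) and more TCF/LEF sites (17.4% against 10.4%, odds ratio 1.93). RUNX sites were more frequent on both sides, in 37.1% of higher and 39.5% of lower peaks against 28.3% (odds ratios 1.39 and 1.67).

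edgeR called 1433 of 4172 peaks, 684 higher and 749 lower in iLTiP, and with pairs as 1 sample 539 and 594. The split turned to 759 and 702 with DESeq2 size factors, 500 and 456 with cyclic loess, 416 and 280 by DESeq2 and 883 and 640 with the GC trend removed. Leaving out iLTiP replicate 1 gave 853 and leaving out iILCP replicate 1 gave 864; those are the deepest libraries and stood apart from their partners.

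Whether the lineage contrast differs in size between both pairs was tested directly, as LTiP against ILCP minus iLTiP against iILCP, in which a genotype effect equal in both lineages cancels. An effect of genotype or its batch that differs between lineages does not cancel and was not tested. The Il17f peak at 20759431 contrasted less in the LTiP and ILCP pair (log2 change 0.91 there and 2.71 in the iLTiP and iILCP pair; difference −1.80 ± 0.22, adjusted p = 6.76e-08). Il17a at 20725511 changed by 0.06 ± 0.19 between LTiP and ILCP and by 1.60 ± 0.22 between iLTiP and iILCP (difference −1.54 ± 0.29, adjusted p = 5.01e-04). A Sulf1 intron peak at 12808913 pointed in opposite directions, 1.35 ± 0.20 and −1.41 ± 0.41 (difference 2.76 ± 0.44, adjusted p = 4.88e-05). At Icos the peak at 61101669 contrasted more between LTiP and ILCP (−2.88 against −1.60; difference −1.27 ± 0.32, adjusted p = 0.0151, and 0.146 with pairs as 1 sample).

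Of the LTi and ILC3 list 6 of 44 peaks had a smaller log2 difference in LTiP against ILCP and 0 a larger one, 13 when adjusted over the list alone (camera adjusted p = 3.33e-05, and 0.0345 with an estimated correlation). The ILC precursor list had 2 of 48 peaks below 0 and 0 above, 6 when adjusted over the list alone (camera adjusted p = 0.0266, but adjusted p = 0.0838 with an estimated correlation). TCF/LEF sites lay near the centre of 16 of 41 peaks with a positive difference (39.0% against 11.2% of unchanged peaks; odds ratio 4.71, 2.31 to 9.34, exact test, adjusted p = 5.36e-05), a call lost with pairs as 1 sample, where 2 of 10 peaks had a site (odds ratio 2.04, 0.207 to 10.5, adjusted p = 0.393). Peaks with a negative difference carried more ROR sites (7 of 56, 12.5% against 3.2%; odds ratio 3.71, 1.38 to 8.51, adjusted p = 0.0115) and RUNX sites (51.8% against 31.5%; odds ratio 2.12, 1.2 to 3.75, adjusted p = 0.0132), and with pairs as 1 sample the 9 such peaks were too few to test. edgeR called 97 peaks, 41 above and 56 below 0. With pairs as 1 sample 19 passed, 10 above and 9 below, and DESeq2 called 11. The count was 60 without LTiP replicate 1, 51 without LTiP replicate 2 and 54 without ILCP replicate 2.

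RORCp_aLP were compared with Flt3nRORCn_aLP, which by label differ in Rorc, to see what chromatin goes with the Rorc-positive state. The IL-17 locus was more open in RORCp_aLP: the Il17f peak at 20759431 held 171 ± 3.25 normalised reads in RORCp_aLP and 14.3 ± 1.04 in Flt3nRORCn_aLP (log2 change 3.56 ± 0.24, adjusted p = 4.87e-18). The Il17a peak at 20725511 held 45.7 ± 11.5 against 4.91 ± 0.555 reads (3.19 ± 0.42, adjusted p = 2.47e-08). Il1r1 had 8 of 27 peaks higher and 1 lower, with 296 ± 2.47 against 76.1 ± 3.71 reads at the intron peak at 40283623–40284867 (1.95 ± 0.18, adjusted p = 4.95e-13). Stat1 fell at its intron peak at 52150578, with 12.9 ± 0.224 against 76.5 ± 6.89 reads (−2.55 ± 0.29, adjusted p = 7.88e-10).

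The peaks of Ncoa2, a nuclear receptor coactivator gene (3.54 ± 0.37), Sbspon (3.10 ± 0.36), the Zap70 promoter (1.83 ± 0.29), Il1rl1 at 40397336 (1.26 ± 0.21) and Icos at 60989868 (1.04 ± 0.16) were also higher in RORCp_aLP. Those of Ino80dos (−2.45 ± 0.37), Coa5 (−2.44 ± 0.34) and Rfx8, a gene of the RFX family (−2.24 ± 0.30), were lower. In the LTi and ILC3 list 16 of 44 peaks were higher and 1 lower, 22 when adjusted over the list alone (camera adjusted p = 8.91e-11, and 0.00871 with an estimated correlation). The ILC precursor list had 9 of 48 higher and 2 lower, 13 when adjusted over the list alone (camera adjusted p = 0.00708, but adjusted p = 0.0588 with an estimated correlation). The cytokine receptor list had 17 of 66 higher and 4 lower, 23 when adjusted over the list alone (camera adjusted p = 5.86e-05, but adjusted p = 0.0838 with an estimated correlation). ROR sites lay near the centre of 56 of 289 peaks higher in RORCp_aLP (19.4% against 2.3% of unchanged peaks; odds ratio 9.47, 6.43 to 13.9, exact test, adjusted p = 3.68e-25) and of 0 of 274 lower peaks, for which the interval of the odds ratio ends at 0.565 (adjusted p = 0.00899). With sites anywhere in the peak 8 lower peaks had one and that call was lost (odds ratio 0.577, 0.243 to 1.18, adjusted p = 0.232). RUNX sites were also more frequent in the higher peaks (45% against 30.4%, odds ratio 1.77). edgeR called 563 peaks, 289 higher and 274 lower, with pairs as 1 sample 222 and 205, and under total count 254 and 304. The count was 346 without Flt3nRORCn_aLP replicate 2 and 297 without RORCp_aLP replicate 1.

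rEILP were set against the same Flt3nRORCn_aLP. Fzd7, a Wnt receptor gene, was higher in rEILP, with 116 normalised reads against 20.4 ± 4.89 at the intergenic peak at 59406624–59407369 (log2 change 2.48 ± 0.22, adjusted p = 1.84e-13). An Il1r1 intron peak at 40294449–40295529 held 225 against 84.3 ± 5.79 reads (1.40 ± 0.16, adjusted p = 4.08e-10), although 6 of the 27 Il1r1 peaks were lower and 3 higher. Sox17, a transcription factor gene of endoderm and endothelium, was lower in rEILP at 4490461–4490905, with 19.3 against 112 ± 6.65 reads (−2.51 ± 0.23, adjusted p = 5.57e-13). Il18r1, which encodes a subunit of the IL-18 receptor, was lower at its intron peak at 40469885 (−1.54 ± 0.19, adjusted p = 2.47e-09).

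Mcmdc2 (2.62 ± 0.29), Mir6898 (2.37 ± 0.30), St18, a zinc finger transcription factor gene (2.16 ± 0.23), Cd28 at 60657095 (2.57 ± 0.40) and Icos at 61146063 (1.73 ± 0.27) had peaks higher in rEILP. Cpa6, a carboxypeptidase gene (−3.44 ± 0.35), Alkal1 (−2.41 ± 0.32), Arhgef4 (−2.26 ± 0.30), Cavin2 (−2.25 ± 0.21) and Zap70 at 36796758 (−1.93 ± 0.36) had lower ones. The LTi and ILC3 list had 4 of 44 peaks higher and 7 lower, 11 when adjusted over the list alone, and no list passed camera (LTi and ILC3 adjusted p = 0.469). Sites for TCF/LEF lay in 16.9% of higher and 11.1% of unchanged peaks (odds ratio 1.56, 1.16 to 2.08, exact test, adjusted p = 0.00568, but odds ratio 1.34, 0.907 to 1.92, adjusted p = 0.202 with pairs as 1 sample), and RUNX sites in 44.5% of lower and 30.3% of unchanged peaks (odds ratio 1.84, adjusted p = 2.28e-09). edgeR called 962 peaks, 420 higher and 542 lower. DESeq2 size factors turned that split to 526 higher and 450 lower, DESeq2 to 233 and 221 and removal of the GC trend to 478 and 472, and with pairs as 1 sample it was 255 and 334. The count was 593 without Flt3nRORCn_aLP replicate 2 and 575 without rEILP replicate 2.

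RORCp_aLP and rEILP were compared with each other directly. Il17f held 171 ± 3.25 normalised reads in RORCp_aLP and 13.1 in rEILP at the peak at 20759431 (log2 change 3.69 ± 0.25, adjusted p = 1.54e-18). The Il1r1 intron peak at 40283623 held 296 ± 2.47 against 50.3 reads (2.57 ± 0.19, adjusted p = 1.19e-16), with 11 of 27 Il1r1 peaks higher and 2 lower. Il1r2, the decoy receptor gene for IL-1, was lower in RORCp_aLP at the intergenic peak at 40030312–40030648, with 15.3 ± 1.53 against 81.8 reads (−2.42 ± 0.31, adjusted p = 9.32e-09). Peaks of Il17a (3.37 ± 0.43), Cpa6 (3.42 ± 0.38), Sbspon (3.24 ± 0.37), Aff3 (2.88 ± 0.42) and Il18r1 (1.05 ± 0.16) were higher, and those of Mir6898 (−3.13 ± 0.38), Icos at 61146063 (−1.92 ± 0.31) and Cd28 at 60803881 (−1.51 ± 0.23) lower.

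The LTi and ILC3 list had 22 of 44 peaks higher in RORCp_aLP and 2 lower, 28 when adjusted over the list alone (camera adjusted p = 1.37e-10, and 0.00871 with an estimated correlation). For the cytokine receptor list 20 of 66 were higher and 3 lower, 27 when adjusted over the list alone (camera adjusted p = 0.00158, but adjusted p = 0.149 with an estimated correlation). ROR sites lay in 11.1% of higher and 2.3% of unchanged peaks (odds ratio 5.05, 3.46 to 7.33), and RUNX sites in 50.6% against 29.7% (odds ratio 2.25). edgeR called 947 peaks, 530 higher and 417 lower, and with pairs as 1 sample 356 and 300. The split turned to 449 and 483 with DESeq2 size factors and to 440 and 494 under total count. Without RORCp_aLP replicate 2 the count was 596, and without rEILP replicate 2 it was 588.

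Flt3nRORCn_aLP and Flt3pRORCn_aLP differ by label in Flt3. edgeR called 0 of 4172 peaks between them, with 285 at an unadjusted p under 0.05, and DESeq2 called 0 with 75; cyclic loess called 4 and a fit of these groups alone 16, and without Flt3nRORCn_aLP replicate 2 edgeR called 1. The lowest p at Icos was at its peak at 61002930, with 59.7 ± 1.88 normalised reads against 85.6 (log2 change −0.53 ± 0.19, adjusted p = 0.474). At Il17f the peak at 20796959 held 45 ± 9.87 against 34.2 reads (0.36 ± 0.25, adjusted p = 0.809). No peak of the LTi and ILC3 list passed when adjusted over the list alone, and its camera adjusted p was 0.123. Of the ILC precursor list 1 of 48 passed in that way, an Il18rap peak at 40490802 with 6.80 ± 1.63 against 0.452 reads. In simulated counts at these depths edgeR found 23% of 1.5-fold, 52.8% of 2-fold and 86.4% of 4-fold changes between these populations at a dispersion of 0.005, and 12.2%, 41.8% and 81.5% at 0.013, so most 1.5-fold differences would be missed at this depth. Each draw held 200 changed peaks and a shifted list of 44, which eases the threshold after adjustment. If fewer peaks truly differ, the share found would be lower than these values.

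iLTiP were compared with RORCp_aLP, 0.57 away on the distance scale above. Il1r1 was higher in iLTiP at the peak at 40210517, with 224 ± 15.5 normalised reads against 57.7 ± 14.6 (log2 change 1.96 ± 0.19, adjusted p = 5.35e-12), and 6 of its 27 peaks were higher and 0 lower. The promoter of Zap70, a kinase gene of T cell receptor signalling, held 139 ± 10.6 against 61.5 ± 15.3 reads (1.13 ± 0.19, adjusted p = 3.77e-05). Cavin2, a gene of caveolar membranes, was lower at its peak at 51148517, with 27.2 ± 10.2 against 195 ± 59.3 reads (−3.01 ± 0.22, adjusted p = 1.75e-16). Peaks of Fhl2 (2.49 ± 0.43), Fzd7 at 59436287 (2.21 ± 0.30), Aff3 at 38402807 (2.13 ± 0.33) and Cd28 at 60750040 (2.66 ± 0.55) were higher in iLTiP, and the Cpa6 peak at 10700003 lower (−3.12 ± 0.35).

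In the LTi and ILC3 list 10 of 44 peaks were higher in iLTiP and 0 lower, 13 when adjusted over the list alone (camera adjusted p = 3.57e-05, and 0.0432 with an estimated correlation). The cytokine receptor list had 8 of 66 higher and 0 lower, 9 when adjusted over the list alone (camera adjusted p = 3.96e-04, but adjusted p = 0.109 with an estimated correlation). TCF/LEF sites lay in 24.8% of higher and 10.7% of unchanged peaks (odds ratio 2.56, 1.83 to 3.56), and ROR sites in 12.6% against 2.9% (odds ratio 4.42, 2.75 to 6.94). edgeR called 336 peaks, 230 higher and 106 lower, and with pairs as 1 sample 165 and 60. The count was 84 without RORCp_aLP replicate 2 and 99 without iLTiP replicate 1.

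iILCP were compared with rEILP in the same way. Icos was higher in iILCP, with 14 of 29 peaks higher and 5 lower and 40.3 ± 9.96 against 5.27 normalised reads at the intergenic peak at 61022270–61022943 (log2 change 2.96 ± 0.38, adjusted p = 3.59e-09). A peak at 60882809–60883176 assigned to Ctla4, an inhibitory receptor gene next to Icos, held 32.2 ± 7.51 against 4.36 reads (2.92 ± 0.42, adjusted p = 5.68e-08). The Il1r1 intron peak at 40294449 was lower in iILCP, with 75.9 ± 11.1 against 225 reads (−1.61 ± 0.15, adjusted p = 1.29e-12), although 11 of 27 Il1r1 peaks were higher and 3 lower. Il1r2 was lower at 40037819 (−2.26 ± 0.25, adjusted p = 1.16e-10).

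Il17a at 20725511 (2.52 ± 0.42), the Il17f promoter at 20784058 (1.65 ± 0.27), Creb1 (2.96 ± 0.32), Sbspon (2.86 ± 0.34), the Zap70 promoter (1.94 ± 0.25), Il18r1 at 40463878 (1.18 ± 0.17) and Cd28 at 60776917 (1.66 ± 0.20) had peaks higher in iILCP. Lman2l (−2.81 ± 0.24), Tbc1d8 (−2.42 ± 0.28), Tram1 (−2.28 ± 0.23), Il1rl1 at 40415515 (−1.69 ± 0.23) and Mcm3, a gene of the replicative helicase (−1.35 ± 0.18), had lower ones. Of the LTi and ILC3 list 20 of 44 peaks were higher and 4 lower, 25 when adjusted over the list alone, and of the ILC precursor list 21 of 48 higher and 6 lower, 29 when adjusted over the list alone; neither passed camera (adjusted p = 0.128 and 0.0906). TCF/LEF sites lay in 18.9% of higher and 9.6% of unchanged peaks (odds ratio 2.22, 1.80 to 2.75), RUNX sites in 44.7% against 28.2% (odds ratio 2.04) and GATA sites in 30.0% against 20.9% (odds ratio 1.63). edgeR called 1778 peaks, 1085 higher and 693 lower, and with pairs as 1 sample 799 and 507. DESeq2 size factors gave 926 and 879 and moved the median log2 change over all peaks from 0.15 to 0.03. The split turned to 449 and 521 by DESeq2, 748 and 757 with only these groups in the fit and 853 and 942 with the GC trend removed. Without iILCP replicate 1 the count was 966.

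**Figure D3:**
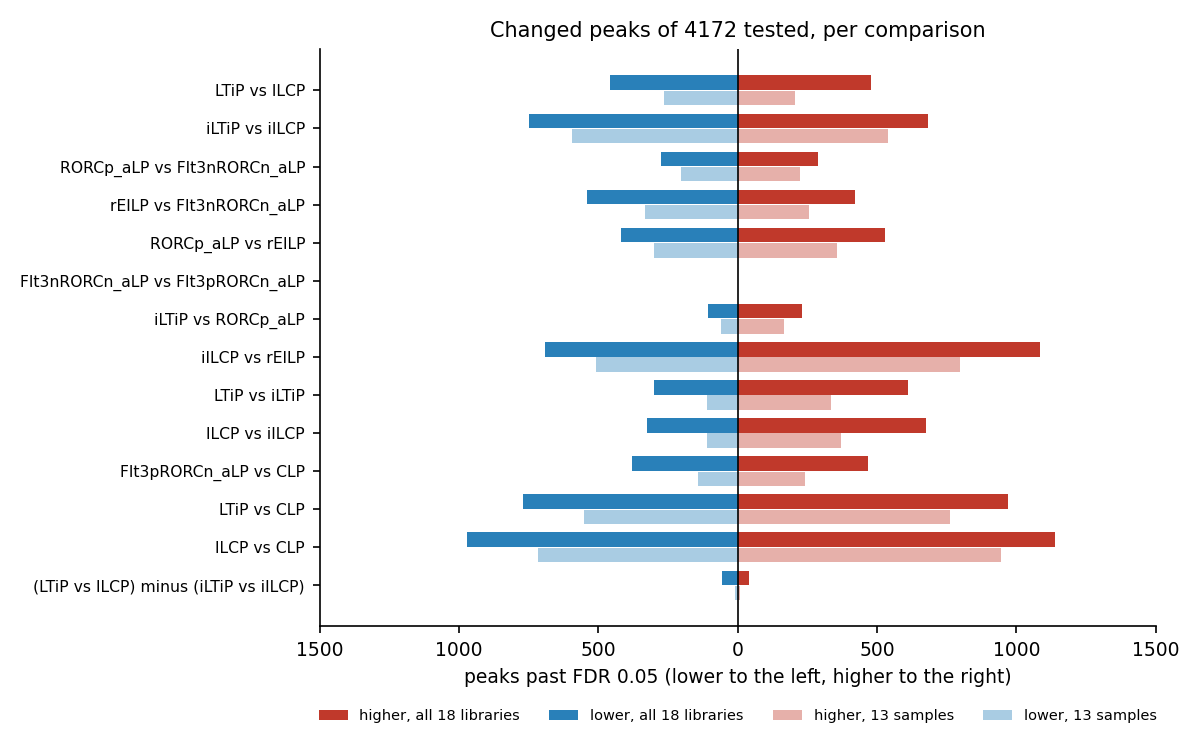
Peaks higher (right) and lower (left) in the population named first of each comparison, at an FDR of 0.05 of 4172 tested; saturated bars take all 18 libraries as samples and pale bars take the 5 indistinguishable pairs as 1 sample each (13 samples). Counts ran from 0 for Flt3nRORCn_aLP against Flt3pRORCn_aLP to 1138 higher and 973 lower for ILCP against CLP.

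LTiP against iLTiP and ILCP against iILCP set populations whose names differ in the prefix i side by side, but they also cross reporter genotypes. A Sulf1 intron peak at 12808913–12809697 held 197 normalised reads in LTiP and 9.17 ± 4.08 in iLTiP (log2 change 4.66 ± 0.30, adjusted p = 2.21e-19). Il1r1 was higher in LTiP at its intron peak at 40243394–40244031, with 232 against 30.6 ± 9.22 reads (2.79 ± 0.22, adjusted p = 3.43e-15). That peak was also higher in ILCP than in iILCP, with 97.6 against 12.5 ± 11.6 reads (2.63 ± 0.26, adjusted p = 7.28e-12). Il17f at 20759431 held 213 reads in ILCP and 36.7 ± 1.30 in iILCP (2.54 ± 0.17, adjusted p = 4.97e-19), and Icos at 61101669 held 244 against 86.0 ± 5.93 (1.53 ± 0.14, adjusted p = 6.96e-13).

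Peaks of Nck2 (3.51 ± 0.26), Phf3 (3.50 ± 0.28), Tmeff2 (3.35 ± 0.28), Ctla4 at 60882809 (2.89 ± 0.30), Zap70 at 36761578 (2.63 ± 0.22) and Icos at 61016578 (2.65 ± 0.36) were higher in LTiP than in iLTiP. The 5 largest falls named by rule in LTiP, at Efhc1, Gls, Map4k4, Aox3 and Bag2, were each lost without iLTiP replicate 1. Slc9a2 (3.05 ± 0.30), Hibch (2.96 ± 0.26), Mir133b (2.79 ± 0.17), Il17a at 20725511 (1.99 ± 0.21) and the Zap70 promoter (2.02 ± 0.15) had peaks higher in ILCP than in iILCP, and Pard3b (−2.22 ± 0.43) and Pikfyve, a lipid kinase gene (−1.41 ± 0.31), had lower ones. For LTiP against iLTiP the LTi and ILC3 list had 18 of 44 peaks higher and 3 lower, 25 when adjusted over the list alone (camera adjusted p = 2.51e-04, but adjusted p = 0.0838 with an estimated correlation), and the cytokine receptor list 22 of 66 higher and 4 lower, 27 when adjusted over the list alone (camera adjusted p = 0.00843, but adjusted p = 0.225 with an estimated correlation). For ILCP against iILCP the LTi and ILC3 list had 21 higher and 3 lower, 25 when adjusted over the list alone (camera adjusted p = 1.07e-10), the ILC precursor list 20 of 48 higher and 2 lower, 26 when adjusted over the list alone (camera adjusted p = 4.47e-06), and the cytokine receptor list 27 higher and 7 lower, 35 when adjusted over the list alone (camera adjusted p = 1.36e-05). With an estimated correlation the camera adjusted p for ILCP against iILCP were 0.00559, 0.00559 and 0.0363 in that order.

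ROR sites lay in 9.5% of peaks higher in LTiP than in iLTiP and 2.2% of unchanged ones (odds ratio 4.92, 3.37 to 7.15), and in 9.9% of peaks higher in ILCP than in iILCP against 2.3% (odds ratio 4.72, 3.29 to 6.77). The gain was not confined to ROR. Peaks higher in LTiP also passed for TCF/LEF (odds ratio 1.99), RUNX (1.37) and ETS (1.34), but not for GATA (1.11). Those higher in ILCP also passed for TCF/LEF (1.47), GATA (1.62), RUNX (1.55) and ETS (1.42). edgeR called 911 peaks for LTiP against iLTiP, 610 higher and 301 lower, and with pairs as 1 sample 335 and 111. Removal of the GC trend gave 452 and 382, and scaling by total count turned the split to 385 higher and 622 lower and moved the median log2 change from 0.03 to −0.19. For ILCP against iILCP it called 1003, 676 higher and 327 lower, and with pairs as 1 sample 372 and 110; total count gave 379 and 719 with a median of −0.26 against −0.02, and cyclic loess 365 and 272. The LTiP against iLTiP count was 371 without iLTiP replicate 1 and 417 without LTiP replicate 2, and the ILCP against iILCP count was 644 without ILCP replicate 1 and 449 without ILCP replicate 2.

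Flt3pRORCn_aLP against CLP also crosses genotypes. Ncoa2 was higher in Flt3pRORCn_aLP at its intergenic peak at 13465002–13465490, with 91.3 normalised reads against 11.3 (log2 change 2.99 ± 0.30, adjusted p = 8.01e-12, and 3.17e-07 with pairs as 1 sample). Mrpl15, a mitochondrial ribosomal protein gene, was lower at 4774824–4775938, with 79.6 against 373 reads (−2.19 ± 0.15, adjusted p = 6.7e-18, and 7.40e-09 with pairs as 1 sample). Il1r1 split, higher at its intron peak at 40236276 (2.44 ± 0.48, adjusted p = 1.02e-04, and 0.00193 with pairs as 1 sample) and lower at its promoter peak at 40224610 (−1.18 ± 0.20, adjusted p = 4.48e-06, and 0.00334 with pairs as 1 sample). Tbc1d8 (2.55 ± 0.31), Bzw1 (2.43 ± 0.41), Il1rl1 at 40415515 (1.44 ± 0.24) and Cd28 at 60735851 (1.06 ± 0.21) had peaks higher in Flt3pRORCn_aLP, and Abi2 (−2.41 ± 0.28), Xkr4 (−2.27 ± 0.32) and Jph1 (−2.21 ± 0.26) had lower ones. The cytokine receptor list had 11 of 66 peaks higher and 2 lower, 13 when adjusted over the list alone (camera adjusted p = 0.0193, but adjusted p = 0.225 with an estimated correlation), and the LTi and ILC3 list 6 of 44 higher and 2 lower, 8 when adjusted over the list alone (camera adjusted p = 0.419). Higher peaks carried RUNX sites more often (41% against 31.3%, odds ratio 1.41) and lower peaks ETS sites (56.1% against 44.3%, odds ratio 1.63). edgeR called 846 peaks, 468 higher and 378 lower, and with pairs as 1 sample 242 and 143. The count was 476 without CLP replicate 1, 524 without CLP replicate 2, 549 without Flt3pRORCn_aLP replicate 1 and 474 without Flt3pRORCn_aLP replicate 2.

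LTiP and ILCP were each compared with CLP, within one genotype. The Il1r1 peak at 40210517 held 10.3 normalised reads in CLP, 449 in LTiP (log2 change 5.43 ± 0.23, adjusted p = 8.79e-29, and 2.21e-18 with pairs as 1 sample) and 299 in ILCP (4.85 ± 0.24, adjusted p = 6.8e-26, and 1.04e-16 with pairs as 1 sample). Il17f at 20759431 rose from 19.1 reads to 400 in LTiP (4.40 ± 0.21), and Icos at 61030371–61031406 from 9.47 to 172 in ILCP (4.22 ± 0.26, adjusted p = 1.75e-21, and 1.15e-14 with pairs as 1 sample). Mrpl15 at 4774824 fell from 373 reads to 34.5 in LTiP (−3.40 ± 0.19, adjusted p = 3e-23, and 1.28e-14 with pairs as 1 sample) and to 40.5 in ILCP (−3.20 ± 0.17, adjusted p = 1.92e-24, and 1.17e-14 with pairs as 1 sample).

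In LTiP, peaks of Il17a at 20740264 (4.54 ± 0.21), the Zap70 promoter (4.39 ± 0.21), Icos at 61030371 (4.14 ± 0.28) and Il18r1 at 40475367 (2.50 ± 0.16) were higher, and those of Arhgef4, an exchange factor gene (−4.30 ± 0.31), and Col19a1 at 24553451 (−3.08 ± 0.31) lower. In ILCP, peaks of Paqr8 (5.53 ± 0.25), Unc80 (5.30 ± 0.31), Il17a at 20740264 (4.18 ± 0.21) and Il18r1 at 40463878 (2.76 ± 0.21) were higher, and those of Mir467e (−3.81 ± 0.30), Cpa6 (−3.71 ± 0.28) and Arhgef4 (−3.50 ± 0.24) lower. No fold is given for a Creb1 peak at 64412354, which held 1.15 normalised reads in CLP and 140 in LTiP. For LTiP the LTi and ILC3 list had 32 of 44 peaks higher and 2 lower, 35 when adjusted over the list alone (camera adjusted p = 6.75e-15), the ILC precursor list 26 of 48 higher and 2 lower, 29 when adjusted over the list alone (8.32e-06), and the cytokine receptor list 44 of 66 higher and 3 lower, 48 when adjusted over the list alone (1.16e-11). For ILCP the LTi and ILC3 list had 26 higher and 8 lower, 34 when adjusted over the list alone (5.35e-06), the ILC precursor list 31 higher and 3 lower, 36 when adjusted over the list alone (2.16e-06), and the cytokine receptor list 42 higher and 10 lower, 53 when adjusted over the list alone (4.5e-06). With an estimated correlation the camera adjusted p of these lists, in that order, were 0.00871, 0.0189 and 0.019 for LTiP. For ILCP they were 0.0373, 0.00871 and 0.0432. The ILC2 list, here Il1rl1 alone, had 10 of 20 peaks higher in each comparison, with 1 lower in LTiP (camera adjusted p = 0.0276, but adjusted p = 0.112 with an estimated correlation) and 3 lower in ILCP (camera adjusted p = 0.0231, but adjusted p = 0.0881 with an estimated correlation).

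ROR sites lay in 9.6% of peaks higher in LTiP than in CLP and 1.8% of unchanged ones (odds ratio 5.59, 3.83 to 8.28), and in 7.1% of peaks higher in ILCP against 2.3% (odds ratio 3.11). TCF/LEF sites lay in 20.8% of peaks higher in ILCP against 8.2% (odds ratio 2.84, 2.28 to 3.55), and in 18.9% of peaks higher in LTiP against 10.1% (odds ratio 2.07, 1.67 to 2.57). RUNX sites were also more frequent in the higher peaks of both (odds ratio 1.81 in LTiP and 2.11 in ILCP). edgeR called 1742 peaks for LTiP against CLP, 970 higher and 772 lower, and with pairs as 1 sample 763 and 551. Total count gave 779 and 1064 with a median log2 change of −0.21 against 0, and removal of the GC trend 880 and 945. edgeR called 2111 for ILCP against CLP, 1138 higher and 973 lower, and with pairs as 1 sample 946 and 717. Total count gave 1003 and 1175 and moved the median from 0 to −0.15, and removal of the GC trend gave 998 and 1186.

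**Figure D4:**
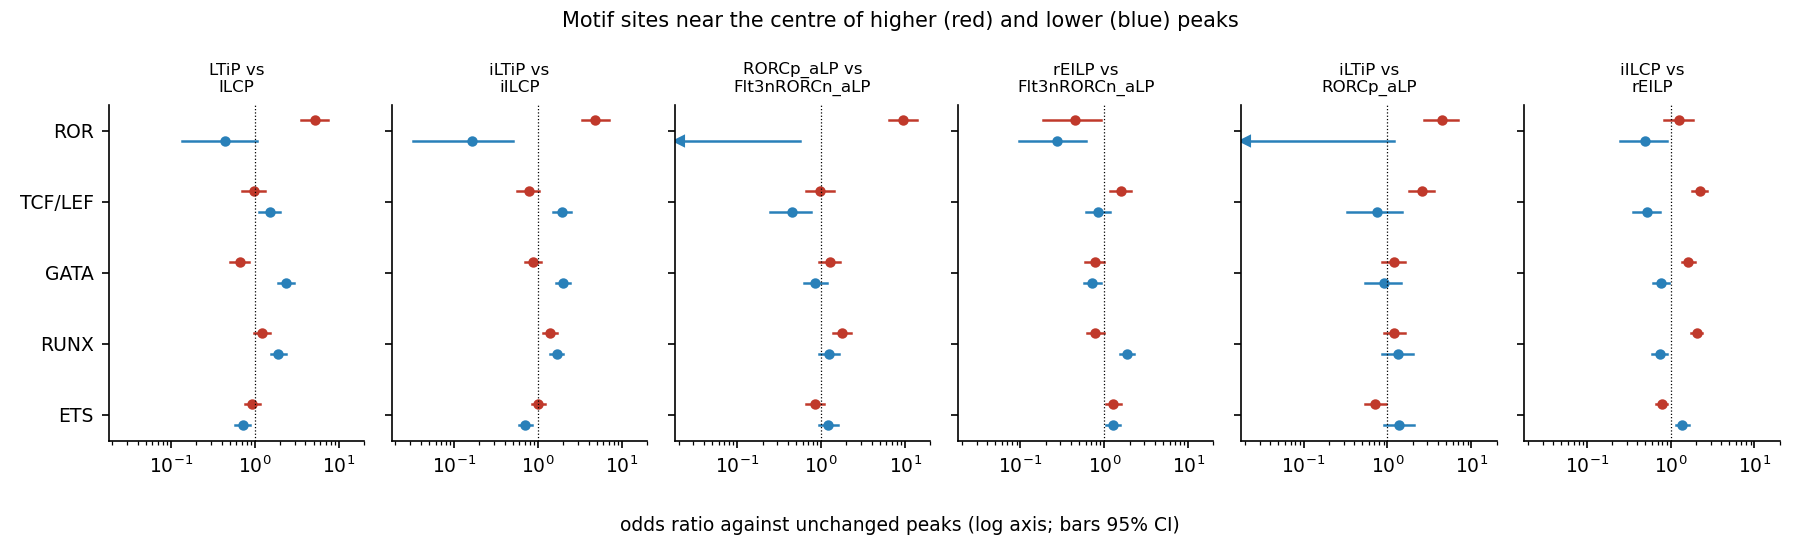
Odds ratios on a log axis, with 95% intervals, for sites of the ROR, TCF/LEF, GATA, RUNX and ETS families within 100 bp of the centre of higher (red) and lower (blue) peaks against unchanged ones, in 6 comparisons; arrowheads mark an odds ratio of 0. ROR reached 9.47 in peaks higher in RORCp_aLP than in Flt3nRORCn_aLP and 5.18 in peaks higher in LTiP than in ILCP.

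The T lineage list (Zap70 and Cd28), the mast cell and basophil list (Il1rl2 alone) and the cell cycle list (Mcm3 alone) passed camera in no comparison, with lowest adjusted p = 0.106 for each. For LTiP against ILCP the T lineage list had 9 of 66 peaks higher and 6 lower, the mast cell and basophil list 2 of 17 higher and 0 lower, and the cell cycle list 2 of 12 higher and 2 lower. Il1rl1 as the ILC2 list had 6 of 20 higher and 5 lower there. In each of the 27 camera calls the median, the mean and the direction of the test had 1 sign. In lists without a call they could differ: for iLTiP against iILCP the ILC2 list had a median of 0.28, a mean of −0.08 and a camera direction upwards. Of the 27 calls, 16 held with an estimated correlation.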

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

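The tests of 1 library read more than once, of small biological variation and of the 3 promoter explanations were chosen after the result was seen, and pairs as 1 sample and limma-trend without loess were added after the data were seen.

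The lineage contrast differed between the LTiP and ILCP pair and the iLTiP and iILCP pair, by an edgeR test of the difference itself, at 97 peaks, which fell to 60 without LTiP replicate 1, 51 without LTiP replicate 2 and 54 without ILCP replicate 2. These pairs also come from different reporter genotypes, so an effect of genotype or its batch that differs between lineages is confounded with this difference and was not tested. Differences are log2 LTiP against ILCP minus iLTiP against iILCP, with the edgeR adjusted p for all libraries and then for pairs as 1 sample. Sulf1 at 12808913 differed by 2.76 ± 0.44 (4.88e-05 and 0.00156), since the contrast was 1.35 in the LTiP pair and −1.41 in the iLTiP pair. Eya1 at 14218566 differed by 1.99 ± 0.49 (0.0109 and 0.081), with 60.2 ± 2.93 normalised reads in iILCP against 8.87 ± 7.67 in iLTiP. Tmeff2 at 51096620 differed by 1.89 ± 0.39 (0.00161 and 0.0444). Phf3 at 30809976 differed by 1.84 ± 0.38 (0.00161 and 0.0656). Stat4, a transcription factor of IL-12 signalling, differed at 52014392 by 1.72 ± 0.38 (0.0046 and 0.102), with contrasts of 0.97 and −0.75. Col19a1 at 24469326 differed by −2.14 ± 0.37 (1.33e-04 and 0.0054), with contrasts of 1.43 and 3.57.

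Efhc1 at 21012604 differed by −1.94 ± 0.53 (0.0303 and 0.182) and Mir6349 at 39091171 by −1.80 ± 0.42 (0.00713 and 0.105). Both peaks were lower in LTiP and in iLTiP, with contrasts of −3.38 and −1.44 at Efhc1 and −2.73 and −0.92 at Mir6349. Il17f at 20759431 differed by −1.80 ± 0.22 (6.76e-08 and 2.74e-04), with 213 reads in ILCP against 36.7 ± 1.30 in iILCP. Il17a at 20725511 differed by −1.54 ± 0.29 (5.01e-04 and 0.0444), with 103 reads in ILCP against 23.5 ± 8.86 in iILCP. Il1r1 at 40210517 differed by −1.16 ± 0.20 (9.67e-05 and 0.0444). Cd28 at 60750040 differed by −2.10 ± 0.51 (0.0107 and 0.081) and Icos at 61101669 by −1.27 ± 0.32 (0.0151 and 0.146). The LTi and ILC3 list differed downwards (camera adjusted p = 3.33e-05, and 0.0345 with an estimated correlation), and so did the ILC precursor list (camera adjusted p = 0.0266, but adjusted p = 0.0838 with an estimated correlation). Each named peak other than Il17f lost its call under at least 1 alternative.

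The libraries of CLP, LTiP and ILCP differ from their partners by no more than counting error, and in peaks with at least 100 reads by less. Small biological variation between separate samples is argued against as the whole account in CLP and LTiP, because it cannot bring chi-square per degree of freedom under 1. CLP stood at 0.785 ± 0.045 (chi-square lower-tail p = 1.03e-07) and LTiP at 0.843 ± 0.047 (0.000243). ILCP, at 0.915 ± 0.04 (0.016), did not pass the bound set for this, so small variation stays open there. The CLP and LTiP values also argue there against independent reads of 1 library. In those populations 1 library read more than once stays open only where both reads share molecules, which was not tested. In ILCP, the highest of the 3, it stays open either way. Flt3pRORCn_aLP stood at 1.003 ± 0.043 and rEILP at 1.039 ± 0.042 in such peaks. Separate samples with little variation would give those values, and so would independent reads of 1 library. Removal of duplicate reads, which caps dense peaks, also stays open: 4 of 9 populations had a lower ratio in their densest than in their sparsest peaks (the top and bottom of 4 equal parts by reads per bp), 3 of them by more than 2 SE, and 5 had a higher one, again 3 by more than 2 SE, which met the bound set beforehand against it, but that bound was wrong and its reading was changed afterwards, because a pair that varies more than counting error grows with abundance whatever the cap (iLTiP from 1.31 to 2.717, iILCP from 1.608 to 2.937). CLP, LTiP and ILCP, the populations from Zbtb16-EGFP mice, went from 0.946 to 0.791, from 0.98 to 0.84 and from 1.068 to 0.831, as a cap would give. That reason does not cover rEILP and Flt3pRORCn_aLP, whose pairs were also within counting error. They showed no such fall (0.963 ± 0.049 to 1.007 ± 0.044 in rEILP, 0.983 ± 0.048 to 0.97 ± 0.044 in Flt3pRORCn_aLP). A cap that acts alike in every pair would be expected to lower them too. A cap and shared molecules cannot be told apart without read-level data. If each pair was 1 library, which stays open, calls against these populations rest on less replication than the library count. Under a cap their spread would be understated.

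LTiP against iLTiP and ILCP against iILCP share no library, yet their log2 changes correlated over peaks at 0.59 ± 0.012 (0.48 ± 0.015 with second libraries only). Peaks are not independent replicates. In the calls 390 peaks were higher in both where independent lists give 98.8, 114 lower in both where they give 23.6, and 8 opposite. That expectation takes every peak as equally likely to be called, so peaks with more reads, where calls are easier, can raise the overlap. Both contrasts cross genotypes, so a shift of reporter genotype or its batch cannot be told apart from the populations: the mean of both changes correlated at 0.18 ± 0.018 with CLP against Flt3pRORCn_aLP, which crosses them too. A maturation change shared by both lineages, untested by the design within a genotype, stays open as well, since ILCP against iILCP correlated with iLTiP against RORCp_aLP at 0.09 ± 0.019 and LTiP against iLTiP with iILCP against rEILP at 0.35 ± 0.016; this test took an order of populations that no label gives. Promoters moved with both, with a median log2 change of 0.33 ± 0.026 and 0.30 ± 0.026 over 156 promoter peaks (0.13 and 0.07 under total count, where other peaks stood at −0.21 and −0.27), but cyclic loess with limma-trend, which removes trends with abundance, left at most 0.07 ± 0.019 and turned ILCP against iILCP to −0.02 (limma-trend without loess kept 0.32 and 0.30), so that a difference in background that follows abundance stays open for this part, as does a real rise of dense peaks, which loess would remove too. Genotype also stays open for the promoter part, since CLP exceeded Flt3pRORCn_aLP there by 0.12 ± 0.022 (0.07 under cyclic loess). Within 1 genotype, LTiP and ILCP exceeded CLP at promoters by 0.22 ± 0.039 and 0.09 ± 0.033, where other peaks stood at −0.02 and −0.01. Total count gave promoters 0.01 and −0.06 and other peaks −0.23 and −0.16, so promoters stood above other peaks under it too. Cyclic loess gave promoters 0.03 and 0 and other peaks −0.03 and −0.06. Whether promoters rose in absolute terms cannot be told apart from scaling.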

How the results depend on the processing

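Pairs as 1 sample, GC removal, thinning and the 1000 most variable peaks were chosen after seeing the data. Among the counts of changed peaks, the lists, motifs and distances, 123 values stayed within 1.5 times the reported one, or for a distance within the spread between libraries, and 42 did not. DESeq2 called 473 peaks for LTiP against ILCP, 696 for iLTiP against iILCP, 297 for RORCp_aLP against Flt3nRORCn_aLP, 454 for rEILP against Flt3nRORCn_aLP, 524 for RORCp_aLP against rEILP, 108 for iLTiP against RORCp_aLP, 970 for iILCP against rEILP, 390 for LTiP against iLTiP, 387 for ILCP against iILCP, 349 for Flt3pRORCn_aLP against CLP and 11 for the difference of contrasts. An absolute log2 change of at least 1 left 556, 800, 357, 547, 589, 204, 1071, 457, 414 and 484 in that order, without the last. A fit of only the compared groups takes the spread from those groups alone and leaves fewer samples. It gave 899 for iLTiP against iILCP, 16 for Flt3nRORCn_aLP against Flt3pRORCn_aLP, 193 for iLTiP against RORCp_aLP, 650 for ILCP against iILCP and 58 for the difference. Pairs as 1 sample, which leaves fewer samples, gave 471 for LTiP against ILCP, 589 for rEILP against Flt3nRORCn_aLP, 446 for LTiP against iLTiP, 482 for ILCP against iILCP, 385 for Flt3pRORCn_aLP against CLP and 19 for the difference. Thinning, which leaves fewer reads, gave 902 for iLTiP against iILCP, 602 for LTiP against iLTiP, 601 for ILCP against iILCP and 48 for the difference. Cyclic loess gave 4 for Flt3nRORCn_aLP against Flt3pRORCn_aLP, 637 for ILCP against iILCP and 22 for the difference. Promoter peaks alone gave 4 camera calls and an estimated correlation 16, against 27. The distance between LTiP and ILCP libraries was 1.183 over the 1000 most variable peaks against 0.819. Where no construction is named, the cause was not tested.

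Leaving out each library gave 481 to 668 peaks for LTiP against ILCP, 853 to 1596 for iLTiP against iILCP, 297 to 424 for RORCp_aLP against Flt3nRORCn_aLP, 575 to 676 for rEILP against Flt3nRORCn_aLP, 588 to 738 for RORCp_aLP against rEILP, 0 to 1 for Flt3nRORCn_aLP against Flt3pRORCn_aLP, 84 to 445 for iLTiP against RORCp_aLP, 966 to 1924 for iILCP against rEILP, 371 to 1015 for LTiP against iLTiP, 449 to 948 for ILCP against iILCP, 474 to 549 for Flt3pRORCn_aLP against CLP, 1298 to 1486 for LTiP against CLP, 1677 to 1794 for ILCP against CLP and 51 to 140 for the difference. With the replicate block the counts were 926 for LTiP against ILCP, 1431 for iLTiP against iILCP and 89 for the difference. Of 4140 checks of 273 named peaks, 3926 stayed past the threshold, 214 did not and 0 reversed; 90 of the 214 came from leaving out a library, 31 from the fold minimum, 22 from DESeq2 and 21 from pairs as 1 sample. Taking all tested peaks for the principal components changed nothing, since all were in use.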

Other observations

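The test of thinning and those of GC and abundance trends were planned before their results were seen, while the pattern they address was seen in the data.

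Of 156 tested promoter peaks, 61 were higher and 2 lower in LTiP than in iLTiP, so 40.4% changed against 21.1% of other peaks, and 59 were higher and 3 lower in ILCP than in iILCP (39.7% against 23.4%). Against CLP, 48 were higher and 18 lower in LTiP, and 37 higher and 17 lower in ILCP. These splits depend on the scaling. With limma-trend in place of edgeR and TMM scaling kept, a fit chosen after the result was seen, they were 54 and 3, 46 and 1, 48 and 19, and 35 and 16 in that order. Limma-trend with cyclic loess gave 10 higher and 6 lower in LTiP than in iLTiP and 12 and 8 in ILCP than in iILCP, and against CLP 30 and 34 in LTiP, a reversal, and 33 and 28 in ILCP. Total count, with the shift of all peaks left in, gave 18 and 7, 15 and 14, 25 and 32, and 28 and 30 in that order, a reversal in both against CLP. There the median of other peaks against CLP was −0.23 in LTiP and −0.16 in ILCP, so that reversal goes with a shift of all peaks and not of promoters alone. The Zap70 promoter peak at 36760341 held 16.9 normalised reads in CLP, 359 in LTiP and 259 in ILCP.

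Peaks of the sort loci and of main lineage genes stand in the annotation of the whole peak set, without per-library values used here. Rorc had 10 peaks, Zbtb16 41, Tcf7 22, Flt3 15, Gata3 57 and Tox, a gene of ILC development, 111. Of the Tox peaks 63 carried a GATA site, 27 a TCF/LEF site and 9 a ROR site anywhere in the peak. Over all 214321 peaks 63.5% held an ETS site, 48.6% a RUNX site, 43.9% a GATA site, 20.9% a TCF/LEF site and 6.7% a ROR site. Promoter peaks held a RUNX site near the centre in 13.9%, other peaks in 31.6%.

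The first libraries of iLTiP and iILCP, 2.83 and 2.49 times as deep as the second, deviated from their second libraries at the same peaks (correlation over peaks 0.20 ± 0.016). Depth alone is argued against, since after thinning to the second libraries' depth the correlation was 0.15 ± 0.0087 (SD over 20 draws). GC content and background that follows abundance are argued against as the whole cause, since removing their trends left 0.20 ± 0.017 and 0.18 ± 0.016. A shared preparation of both first libraries, which the labels do not give, stays open, and no biological explanation was tested.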
